A study of Mus musculus with 6 samples.

How the data were processed

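RNA was extracted with the Qiagen RNeasy kit, copied into biotin-labelled cRNA and hybridised to Affymetrix 3′ expression arrays, per the labels' protocols. Each of the 6 arrays was hybridised with total RNA of 1 sample, 3 from cells with an empty vector (EV) and 3 from cells with Cre. The groups and the replicate numbers came from the sample titles. The titles number the repeats but do not say whether these were separate cultures or animals, so the p-values measure the spread between these samples, which may be technical.

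The values are log2 signals, 1 column per array, as the authors deposited them. Per the submitters' processing notes they were made with MAS5, a method that summarises the perfect-match and mismatch probes of a probe set into 1 signal; its version and settings are not given in the sources used here. The log base was settled from the values. With base 2, the mean of the linear signals after trimming 2% at each end was between 499.87 and 499.88 on every array. Linear signals under 1 had been set to 1, which gave an exact 0 for 2.55% to 4.39% of the probe sets of an array. MAS5 scaling multiplies each array by 1 factor, so it corrects neither differences that depend on signal level nor differences in the background of dim probe sets. Mismatch subtraction makes dim values noisy. Detection calls were not used here, and the number of arrays limits the precision.

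Of 45101 probe sets, 64 controls were set aside. The platform annotation gave 1 gene symbol for 34945 of the others, several for 932 and none listed here for 9160. Checking the symbols against RefSeq through the Entrez number changed 0 of them. Probe sets whose mean over all 6 arrays lay under the 40th percentile (5.35) were left out as dim, which left 27022, of which 21978 had 1 symbol. Each gene was represented by its brightest such probe set, which gave 10999 genes. Probe sets with the suffix x_at hold probes that also match other transcripts, and those of Srrm4, Ly6g6c, Ncaph2, Tarbp2, Fen1 and Asns, and the brighter one of Igll1, are of this kind. No genome build is involved and no positions are given.

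The comparison was Cre minus EV in limma 3.58.1 under R 4.3.3, with lmFit and eBayes with a trend of variance on level, 2-sided, Benjamini-Hochberg adjustment and a threshold of 0.05. Every limma p printed in the text comes from this test. Bcl6 was read from a fit over all 45037 probe sets, dim or not. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 16 lists with at least 5 tested members, with camera at an estimated correlation and fry beside it. Of the 20 lists, 361 distinct symbols were named, 267 were tested and 22 had no probe set with 1 symbol. Single values were compared between groups with 2-sided exact permutation tests, which cannot go below p = 0.1 with 3 against 3 arrays.

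The groups, the tests, the 20 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule takes Bcl6, and the 12 largest increases and 12 largest decreases among genes past the threshold whose groups do not overlap, leaving out clone names and immunoglobulin variable segments. Where fewer than 5 genes pass in a direction it takes the 10 with the lowest p, as genes that did not pass. Of each list it takes up to 4 members with the lowest p. The fit without EV replicate 1 was among the alternatives fixed then. It is reported in full, with the same naming rule, because EV replicate 1 was seen to lie apart, so the 24 genes named from it were chosen after values were seen. Further settings and 3 further gene lists were added after the data were seen, namely an offset of 16 on the linear scale, array weights and the other settings of the fit without EV replicate 1. The 3 added lists are ATF4, amino acid and one-carbon genes, plasmacytoid dendritic cell markers, and abundant granule and phagocyte genes. The alternatives were quantile normalization, median centring, other variance models, a replicate block, other dim filters, the mean of all probe sets of a gene, all probe sets and leaving out each array.

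The scripts were tested on simulated data for the same 10999 genes, with independent normal noise for each gene and no outlying array. With all 6 arrays, 79% of genes shifted by 1 log2 unit and 100% of those shifted by 2 were recovered, with 11 false calls among 190. Without EV replicate 1, the shares were 91% and 100%, with 17 false calls among 212. The real arrays hold an outlying one, so these shares do not measure what they can detect. Bcl6 differed by −2.66 over all 6 real arrays and did not pass. Of 100 unshifted lists, 1 and 0 had an unadjusted camera p under 0.05 in the respective fits. As the simulated genes were independent, this does not test camera at the correlations of the real lists. Over all 6 arrays these were estimated at 0.45 for the replication list and 0.37 for the mitosis list.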

Results

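Gene expression was measured in mouse pre-B cells from bone marrow whose Bcl6 gene was flanked by loxP sites and which carried TCF3-PBX1, the fusion oncoprotein of a subtype of B cell acute lymphoblastic leukaemia. The cells had received an empty vector (EV, 3 arrays) or Cre recombinase, which removes DNA between loxP sites (Cre, 3 arrays). The single contrast, Cre against EV, asks which transcripts depend on BCL6, a zinc finger repressor of transcription, in these cells. No array held cells given Cre without loxP sites in Bcl6, so effects of Cre itself cannot be told apart from loss of Bcl6. The series title sets the contrast within work on feedback between BCL6 and the pre-B cell receptor. All values are log2 MAS5 signals, and differences are Cre minus EV. The arrays had the same trimmed mean. The median over all probe sets was 6.45 ± 0.11 in EV and 6.72 ± 0.06 in Cre (SD, n = 3, exact permutation p = 0.1, the smallest possible), while the median of the tested genes lay between 9.46 and 9.51 on every array. Centring each array on its overall median shifted the median difference of all tested genes to −0.27, so positive differences smaller than this shift turned negative under that scaling.

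Bcl6 signal was lower on every Cre array than on any EV array. Probe set 1421818_at read 10.45, 7.87 and 7.82 on EV replicates 1 to 3 and 5.92, 6.31 and 5.93 on Cre replicates 1 to 3. The means were 8.72 ± 1.5 and 6.05 ± 0.22 (SD, n = 3), a difference of −2.66 (SE 0.65), or 6.32-fold lower. The second probe set, 1450381_a_at, averaged 8.31 ± 1.5 in EV and 5.86 ± 0.18 in Cre, a difference of −2.45 (SE 0.65), or 5.47-fold lower. Both differences had an adjusted p of 0.407 in limma over all probe sets, and this ranged from 0.156 to 0.758 over the alternative settings. The exact permutation p was 0.1 for each, the smallest that 3 against 3 arrays allow. The Cre readings lay near the dim limit of 5.35, and with an offset of 16 the differences were −2.42 and −2.19 in the respective probe sets. The size of the fold also depended on EV replicate 1. Its Bcl6 signal lay 2.61 and 2.54 above the mean of EV replicates 2 and 3 in the respective probe sets, and without it the folds were 3.46 and 3.04, with an adjusted p of 0.156. Which exons Cre removes, and whether either probe set lies in them, is not given in the sources used here.

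**Figure D1:**
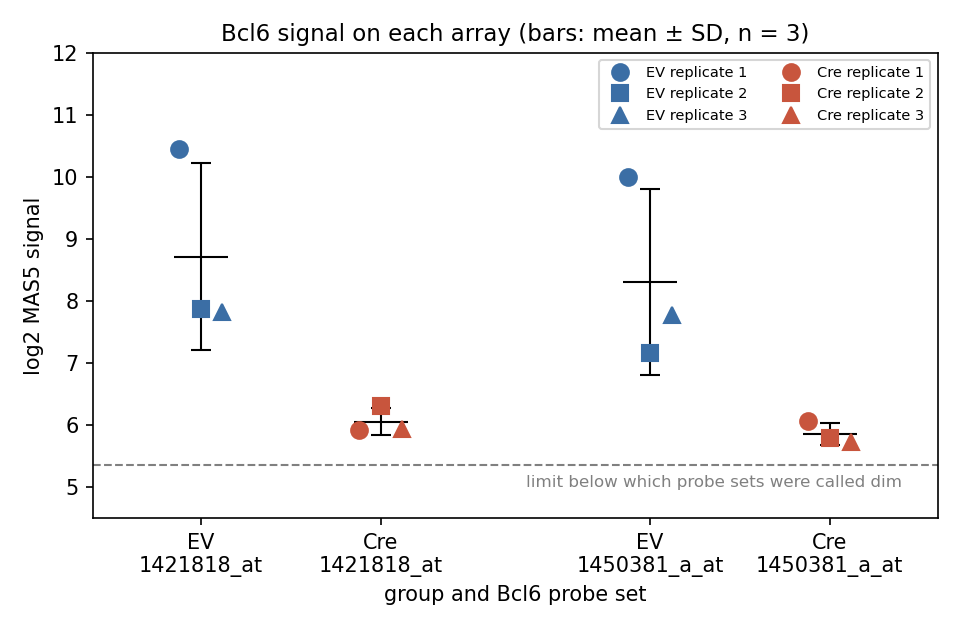
Log2 MAS5 signal of the 2 Bcl6 probe sets on each array, with EV arrays in blue and Cre arrays in red, marker shape giving the replicate number, and bars giving mean ± SD (n = 3). EV replicate 1 reads 10.45 in probe set 1421818_at, the other EV arrays 7.87 and 7.82, and the Cre arrays 5.92 to 6.31, above the dashed dim limit of 5.35.

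With all 6 arrays, the genes with the lowest p in each direction were of mixed function and changed by 1.35-fold to 2.66-fold, and none passed the adjusted threshold. Bcl6, 6.32-fold lower, changed more but was not among them, as its p was higher. Among the 10 with the lowest p on the higher side were Srrm4, a regulator of neuronal splicing, at 5.45 ± 0.08 in EV and 6.86 ± 0.28 in Cre (SD, n = 3), a 2.66-fold difference, and Ly6g6c, a Ly6 family gene, at 6.03 ± 0.10 and 7.14 ± 0.21. The testis actin-like gene Actl7b read 5.51 ± 0.02 and 6.64 ± 0.06. All 3 genes lay close to the dim limit of 5.35 in EV. Arap3, a GTPase-activating protein of Arf and Rho proteins, differed by 1.10 (SE 0.21), the potassium channel gene Kcnj13 by 1.07 (SE 0.21), and the mitochondrial translation gene Rmnd1 by 0.83 (SE 0.18). Heg1, a transmembrane receptor, differed by 0.78 (SE 0.17), the glutamate receptor gene Gria2 by 0.71 (SE 0.15), the forkhead repressor gene Foxn3 by 0.70 (SE 0.14) and the acyl-CoA synthetase gene Acsf2 by 0.69 (SE 0.15). For Foxn3, 2 of 4 probe sets that were not dim had the opposite sign.

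On the lower side, Tarbp2, a partner of Dicer, read 9.41 ± 0.08 in EV and 8.34 ± 0.49 in Cre (SD, n = 3), 2.10-fold lower. Klhl26 differed by −0.69 (SE 0.14), the condensin II gene Ncaph2 by −0.63 (SE 0.12), the tubulin deacetylase gene Hdac6 by −0.63 (SE 0.14) and the O-glycosylation enzyme gene Galnt2 by −0.61 (SE 0.13). The iron-sulfur cluster assembly gene Ciapin1 differed by −0.58 (SE 0.13), Rmdn3 by −0.55 (SE 0.12) and the elongation factor gene Elof1 by −0.53 (SE 0.10). The proteasome adaptor gene Ecpas differed by −0.44 (SE 0.10), as did Fen1, the flap endonuclease of lagging-strand synthesis, also by −0.44 (SE 0.10). For Ncaph2, Galnt2, Tarbp2, Ciapin1, Rmdn3 and Ecpas, 1 other probe set had the opposite sign. Each of these 20 genes had an adjusted p of 0.614 in limma. In all, 0 of 10999 genes passed in limma, against 873 (7.94%) at an unadjusted p under 0.05. Setting EV replicate 1 with Cre replicates 2 and 3 against the rest, which is no comparison of the study, gave 1428 genes at that p. The remaining splits of the arrays into 3 and 3 gave 73 to 722, fewer than the real grouping. The 3 Cre values did not overlap the 3 EV values for 1760 genes (16%, against 10% by chance). Without EV replicate 1 the count was 166, described further on.

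Most DNA replication and mitosis genes read lower in Cre, and these lists passed at the preset correlation only. Both calls were lost with an estimated correlation (adjusted p = 0.891 for each), fry gave an adjusted p of 0.487 for each, and no member of either list passed over all genes tested. Of 24 DNA replication genes tested, 22 lay below 0, with a median of −0.15 (camera adjusted p = 1.37e-05). The members with the lowest p were Fen1, the clamp loader gene Rfc4 at 11.37 ± 0.17 in EV and 10.81 ± 0.19 in Cre, the replication initiation gene Mcm10 at −0.50 (SE 0.14) and the licensing factor gene Cdt1 at −0.30 (SE 0.10). Of 24 G2/M and mitosis genes tested, 21 lay below 0, with a median of −0.19 (camera adjusted p = 2.81e-05). Its lowest p belonged to the spindle checkpoint gene Bub1b at −0.29 (SE 0.10), Cdc20, an activator of the anaphase-promoting complex, at −0.27 (SE 0.10), and the cyclin genes Ccna2 at −0.22 (SE 0.08) and Ccnb2 at −0.21 (SE 0.09). Adjusted over the list alone, 3 replication genes and 0 mitosis genes passed. Without EV replicate 2 the medians shrank to −0.05 for replication and −0.11 for mitosis and both lists still passed, and with the mean of all probe sets of a gene the mitosis median was −0.04. At least 2 lists also passed in 6 of the 9 other splits of the arrays into 3 and 3.

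The 14 other lists tested did not pass with all 6 arrays, and no member of any list passed over all genes tested. The B lineage and progenitor lists passed as higher with quantile normalization. With array weights, the MYC list passed as lower and the differentiation, progenitor and myeloid lists as higher. The known and proposed BCL6 target genes had a median of 0.14 over 22 genes, 15 of them above 0 (adjusted p = 0.641). Bcl2, an inhibitor of apoptosis, differed by −0.48 (SE 0.13) and the chemotactic receptor gene Gpr183 by 0.64 (SE 0.27). The pre-B cell receptor and its proximal signalling genes had a median of −0.06 over 22 genes (adjusted p = 0.423), and passed as lower under median centring, with the adaptor gene Blnk at 0.22 (SE 0.09) and the kinase gene Fyn at −0.52 (SE 0.24). The surrogate light chain genes, named outside the rule after their values were seen, read 13.51 ± 0.11 in EV and 13.52 ± 0.19 in Cre for Vpreb1 (SD, n = 3). For Igll1 the probe sets differed in sign, at −0.03 (SE 0.12) in the brighter one, which also matches other transcripts, and 0.30 (SE 0.17) in the other. The p53 target genes had a median of −0.03 over 19 genes (adjusted p = 0.690), with Mdm2, the ubiquitin ligase of p53, at 0.40 (SE 0.12) and Apaf1 at −0.29 (SE 0.13). Pro-B and progenitor genes had a median of 0.14 over 11 genes (adjusted p = 0.203), with the receptor gene Cd27 at 0.73 (SE 0.29). Genes of differentiation from pre-B to immature B cells had a median of 0.07 over 15 genes (adjusted p = 0.537), with the recombinase gene Rag1 at 1.11 (SE 0.40) and Cd40 at 0.93 (SE 0.36). B lineage transcription factors had a median of 0.01 over 20 genes (adjusted p = 0.735), with Ets1 at 0.26 (SE 0.12).

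Cytokine receptor, STAT5 and RAS signalling genes had a median of 0.15 over 22 genes (adjusted p = 0.763), with the cyclin gene Ccnd3 at −0.32 (SE 0.08) and Socs3, a feedback inhibitor of cytokine receptors, at 0.82 (SE 0.25). MYC targets and ribosome biogenesis genes had a median of −0.01 and a mean of 0.01 over 22 genes, so median and mean differed in sign (adjusted p = 0.826). FOXO target genes, among them Bcl6 itself, had a median of 0.02 over 16 genes and a mean just below 0 (adjusted p = 0.700), with the insulin receptor gene Insr at 0.89 (SE 0.37). Adjusted over the list alone, 1 member passed, and this was Bcl6, the gene targeted by Cre. Interferon response genes had a median of −0.09 over 16 genes (adjusted p = 0.690), with Ifi35 at −0.32 (SE 0.11) and Usp18, which removes ISG15 from proteins, at 0.60 (SE 0.26). NF-kB target genes had a median of −0.06 over 16 genes (adjusted p = 0.930), with Traf1 at 0.51 (SE 0.25). The BCL2 family had a median of −0.11 over 10 genes (adjusted p = 0.379), with Bad, a promoter of apoptosis, at −0.29 (SE 0.15). Plasma cell markers had a median of −0.06 over 10 genes and a mean just above 0 (adjusted p = 0.537), with Creld2 at −0.28 (SE 0.15). Myeloid cell markers had a median of −0.06 over 8 genes (adjusted p = 0.921), with Cd68 at 0.26 (SE 0.21).

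Lists of other cell types with under 5 tested members had no camera test. Of the T and NK cell markers, 4 genes were tested, with Cd247 at −0.20 (SE 0.11) and Il2rb at 0.42 (SE 0.39). Of the stromal cell markers, 3 were tested, and Acta2, the smooth muscle actin gene, read 7.40 ± 0.33 in EV and 8.26 ± 0.15 in Cre (SD, n = 3), which passed adjusted over the list alone but not over all genes (adjusted p = 0.614). The collagen probe sets of Col1a1 and Col1a2 were dim. Of the erythroid and megakaryocyte markers, only Alas2 was tested, at 0.71 (SE 0.28), which passed adjusted over the list alone as its single member but not over all genes (adjusted p = 0.625). Of the sex-linked genes, 3 Y-linked ones were tested, with Eif2s3y at 11.6 ± 0.35 in EV and 11.4 ± 0.09 in Cre, and the Xist probe sets were dim.

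EV replicate 1 lay apart from the other 5 arrays in many genes. Its correlation with them across genes was 0.954 to 0.965, against 0.98 to 0.99 among the other 5, and the first principal component, which set it apart, held 51.6% of the variance. It lay more than 1 log2 unit above every other array for 174 genes and below for 176, against 0 to 3 and 2 to 35 for each other array. The genes given next were named after their values were seen, from those with the widest gaps. The progesterone receptor gene Pgr read 9.50 against 5.30 to 6.63 elsewhere, Mycl 10.28 against 6.30 to 7.58, the chemokine receptor gene Ccr9 10.07 against 6.59 to 7.45, and the macrophage growth factor receptor gene Csf1r 11.35 against 8.14 to 9.11. The scavenger receptor gene Cd36 read 3.33 against 7.08 to 7.78, and the inhibitory receptor gene Btla 3.12 against 5.92 to 6.42. The log2 ratio of the 3′ to the 5′ control probe sets was 1.52 for Gapdh on EV replicate 1 and 0.75 to 1.13 elsewhere. By group it was 1.18 ± 0.32 in EV and 0.85 ± 0.11 in Cre for Gapdh (exact permutation p = 0.2), and 0.23 ± 0.04 and 0.14 ± 0.05 for Actb (exact permutation p = 0.1, SD, n = 3). For pyruvate carboxylase it was 0.82 ± 0.19 and 0.52 ± 0.15 (exact permutation p = 0.2), with EV replicates 2 and 3 at 0.91 and 0.94, above all Cre arrays. For the transferrin receptor it was −0.67 ± 0.11 and −0.70 ± 0.39 (exact permutation p = 0.9).

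**Figure D2:**
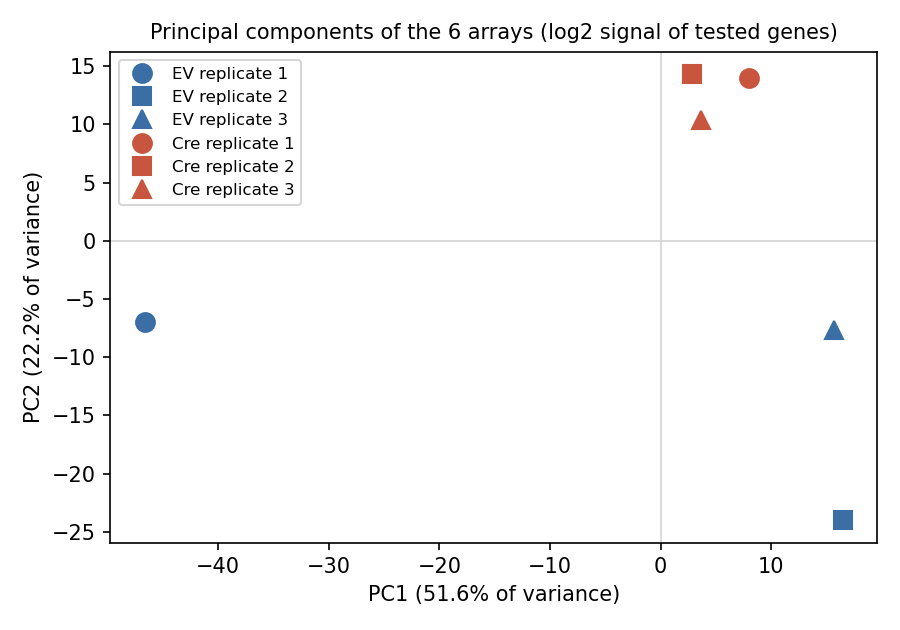
First and second principal components of the log2 signals of the tested genes, 1 point per array, with EV arrays in blue, Cre arrays in red and marker shape giving the replicate number. EV replicate 1 lies alone on the first component (51.6% of the variance), and the second (22.2%) has all 3 Cre arrays above 0 and all 3 EV arrays below it.

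Without EV replicate 1, which leaves 2 EV and 3 Cre arrays, 166 genes passed in limma, 89 higher and 77 lower in Cre, 19 of them by at least 1 log2 unit. Cd33, a sialic acid-binding lectin of myeloid cells, rose 2.29-fold (1.2, SE 0.16), and the paired immunoglobulin-like receptor genes Pilra and Pilrb1 rose 2.18-fold and 2.10-fold. Nme5, a nucleoside diphosphate kinase family gene, rose by 1.82 (SE 0.35) on the deposited scale, but its EV readings of 5.06 and 4.09 lay below the dim limit of 5.35, so the size of its fold is uncertain, and it was 1.31 with an offset of 16. Other increases were those of the serine protease gene Htra3, 2.12-fold, and the transcription factor gene Zfhx3, 2.11-fold. Adam4 rose 2.30-fold and Zfp105 2.29-fold (1.20 for each), and with an offset of 16 each rose by 1.04. Zfp105 read 7.29 on EV replicate 1, within the 7.11 to 7.43 of the Cre arrays. Srrm4, Ly6g6c, Actl7b and the lectin gene Siglecf rose by 1.45, 1.17, 1.14 and 1.21 from EV levels near the dim limit, so the sizes of these folds are uncertain. With an offset of 16, Siglecf (0.96) and Actl7b (0.92) no longer passed. With quantile normalization, only Cd33 and Htra3 of the genes named here as higher still passed. On EV replicate 1 itself, however, Cd33 read 10.93 against 8.74 to 9.24 in Cre, and Siglecf, Pilra, Pilrb1, Nme5 and Zfhx3 likewise lay above all 3 Cre arrays. With all 6 arrays the difference was therefore 0.15 (SE 0.74) for Cd33, 0.07 (SE 0.82) for Siglecf and −0.02 (SE 0.77) for Pilrb1. Of the 166 genes, EV replicate 1 lay on the Cre side of the mean of EV replicates 2 and 3 for 149, and beyond the Cre mean for 108 of these. As the calls rest on EV replicates 2 and 3 too, a majority is expected by construction. Taking as many genes with the largest Cre difference from 1 of these 2 arrays, EV replicate 1 lay on the Cre side of the other for 100 and 112.

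Bcl6 had the largest decrease of this comparison, 3.46-fold (−1.79, SE 0.22, limma adjusted p = 0.02 over the genes tested). With an offset of 16 this difference was −1.58. Lif, a cytokine of the interleukin 6 family, fell 2.72-fold, Tarbp2 2.04-fold and Tubb3 1.79-fold. Asns, asparagine synthetase, fell 1.88-fold (−0.91, SE 0.12), Ctps, CTP synthase, 1.80-fold (−0.85, SE 0.15), Prps1, which makes the ribose phosphate donor of nucleotides, 1.70-fold, and the neutral amino acid carrier gene Slc1a4 1.68-fold. Rasgrp1, an activator of RAS, fell 1.72-fold, the chemokine receptor gene Cxcr5 1.67-fold, the nucleolar gene Lyar 1.66-fold and the methyltransferase gene Smyd5 1.66-fold, with 1 of 3 Smyd5 probe sets of the opposite sign. Apart from Bcl6 and Tarbp2, these genes lay lower on EV replicate 1 than on EV replicates 2 and 3. All of these except Tubb3 also lay lower there than on all 3 Cre arrays. Lif read 3.33 on EV replicate 1, against 7.21 and 6.97 on the other EV arrays and 5.39 to 6.0 in Cre. With all arrays the differences of these genes were therefore smaller, at −0.19 (SE 0.91) for Lif and −0.17 (SE 0.41) for Smyd5. For Cxcr5 the difference was then 0.06 (SE 0.57), of the opposite sign. Of the decreases named here, those of Tarbp2, Ctps, Prps1 and Slc1a4 no longer passed with quantile normalization, and the others did.

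The count of 166 rested on few arrays. It was 0 without EV replicate 2, 0 without EV replicate 3, 823 without Cre replicate 1, 72 without Cre replicate 2 and 7 without Cre replicate 3, and it was 0 without a variance trend or without the dim filter. Leaving out either further EV array leaves 1 EV array, whose spread is then assumed to be that of Cre. Median centring gave 105 genes higher and 3738 lower in Cre (2.73% higher, against 53.6%), as it moved the median of all tested genes to −0.31. By contrast, the mean of the probe sets of each gene gave 256 higher and 133 lower, and all probe sets past the dim filter gave 811 higher and 194 lower. At an unadjusted p under 0.05, 2320 genes (21.1%) differed, and the groups did not overlap for 4359 genes (39.6%, against 20% by chance).

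Without EV replicate 1, 7 lists passed at the preset correlation, 4 of them lower and 3 higher in Cre, and none passed with an estimated correlation. The adjusted p was then 0.194 for the MYC, replication, mitosis and differentiation lists, 0.262 for the myeloid, 0.328 for the cytokine and 0.364 for the progenitor list. MYC targets and ribosome biogenesis genes had a median of −0.33 (camera adjusted p = 1.34e-09), and 5 of 22 fell, with Srm, spermidine synthase, at −0.72 (1.64-fold, SE 0.12), Cad, an enzyme of pyrimidine synthesis, 1.44-fold, Nolc1 1.5-fold, Nop58 1.36-fold and Mybbp1a 1.36-fold. DNA replication genes had a median of −0.27 (adjusted p = 2.24e-09), and 3 of 24 fell, namely Mcm10 1.52-fold, the cyclin gene Ccne1 1.55-fold and Fen1 1.39-fold. G2/M and mitosis genes had a median of −0.26 with all 24 below 0 (adjusted p = 1.99e-08), but none passed over all genes. The topoisomerase gene Top2a differed by −0.37 and the spindle gene Tpx2 by −0.34. Cytokine receptor, STAT5 and RAS signalling genes had a median of −0.19 (adjusted p = 0.0169) with none past the threshold, the kinase gene Pim3 at −0.43 and Cish, a STAT5 target, at −0.42. Adjusted over the list alone, 14 MYC, 11 replication, 13 mitosis and 4 cytokine list members passed. EV replicate 1 lay below the mean of EV replicates 2 and 3 in the same lists, by a median of −0.76 for the MYC list, −0.28 for replication, −0.25 for mitosis and −0.64 for the cytokine list.

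Of 8 myeloid cell markers, 3 rose without EV replicate 1 (median 0.54, camera adjusted p = 0.00150). These were the signalling adaptor genes Tyrobp, 1.51-fold, and Fcer1g, 1.60-fold, and Csf1r, 1.63-fold; Fcgr3 differed by 0.49 without passing. All 15 differentiation genes lay above 0 (median 0.24, adjusted p = 0.00150), none of them past the threshold, with Ly86 at 1.29 (SE 0.35) and the class II gene H2-Ab1 at 0.79 (SE 0.22). Their median was −0.07 after median centring, although the list still passed as higher than other genes. Pro-B and progenitor genes had a median of 0.13 (adjusted p = 0.0169), with Sox4 at 0.36 (SE 0.10) and Cd93 at 0.27 (SE 0.09), and this median was −0.19 after median centring, where the list did not pass. Adjusted over the list alone, 6 myeloid, 2 differentiation and 1 progenitor gene passed. EV replicate 1 lay above the mean of EV replicates 2 and 3 by a median of 1.17 for the myeloid list, 0.79 for differentiation and 0.29 for progenitor genes. The calls of the progenitor and cytokine lists were also lost without EV replicate 2 (adjusted p = 0.187 and 0.157) and without Cre replicate 1 (adjusted p = 0.0848 for both). The cytokine list did not pass after median centring either (adjusted p = 0.0697).

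The other 9 lists tested did not pass without EV replicate 1, although the B lineage factors passed as higher with quantile normalization, and the NF-kB and FOXO target genes with a dim filter at the 60th percentile. The BCL6 target genes had a median of −0.03, a mean of 0.08 and an upward test (adjusted p = 0.965), and 9 members passed adjusted over the list alone but none over all genes. The pre-B cell receptor genes had a median of 0.03 (adjusted p = 0.850), the p53 target genes 0.04 (adjusted p = 0.695), the B lineage factors 0.05 (adjusted p = 0.395), the NF-kB target genes 0.11 (adjusted p = 0.245) and the FOXO target genes 0.18 (adjusted p = 0.132). The interferon genes had a median of 0.14 (adjusted p = 0.554), and Usp18 rose 1.85-fold. The BCL2 family had a median of −0.12 (adjusted p = 0.580) and the plasma cell markers −0.08 (adjusted p = 0.305). Among lists too small to test, the granule protein gene Nkg7 of the T and NK list rose 1.67-fold, with EV replicate 1 at 9.55 above all Cre arrays.

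**Figure D3:**
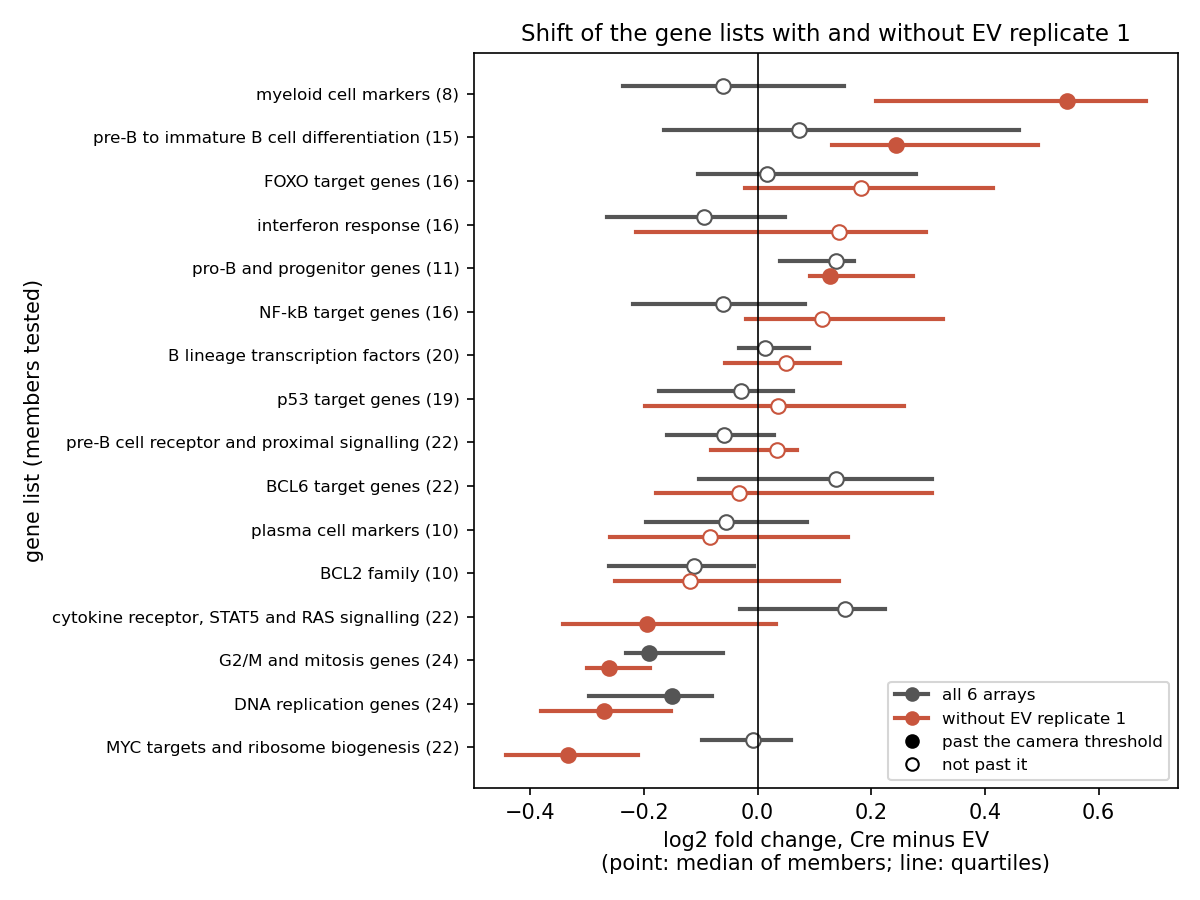
Median log2 difference (Cre minus EV, horizontal axis) of the tested members of each gene list, with lines giving the quartiles, for all 6 arrays in grey and without EV replicate 1 in red; filled points passed camera at the preset correlation. With all arrays the replication (−0.15) and mitosis (−0.19) lists passed at that correlation and not at an estimated one, and without EV replicate 1 also the MYC list (−0.33), the cytokine list (−0.19), and the myeloid (0.54), differentiation (0.24) and progenitor (0.13) lists.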

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

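Offset 16, array weights and every alternative to the comparison without EV replicate 1 were chosen after the data were seen; the others were planned. The count of changed genes over all arrays, 0, stayed 0 except with array weights (562, of them 335 higher and 227 lower in Cre) and without EV replicate 1, so that leaving out 1 array gave 0 to 166. The 2 lists over all arrays became 4 with quantile normalization (B lineage factors and progenitor genes added, both higher), 3 with median centring (the pre-B cell receptor list added, lower), 6 with array weights (MYC, differentiation, progenitor and myeloid added), 0 with an estimated correlation, 0 with fry and 2 to 7 when 1 array was left out. The 166 genes became 34 with quantile normalization, 3843 with median centring, 0 without a variance trend, 1536 with a replicate block, 0 without a dim filter, 389 with the mean of probe sets, 1335 with array weights, 1005 probe sets when all were tested, and 0 to 823 when 1 more array was left out. The 34 genes were all among the 166, and 125 of the 166 were among the 3843. The 7 lists became 0 with an estimated correlation and 2 with fry (mitosis and differentiation). Quantile normalization added the B lineage factors, and the 60th percentile filter the NF-kB and FOXO lists, all higher. With a replicate block the progenitor and cytokine lists did not pass (adjusted p = 0.119 for both), nor did the cytokine list with the 60th percentile filter (0.0692) or the progenitor list with the mean of probe sets (0.106). In the fit without EV replicate 1, the replicate block leaves Cre replicate 1 without a partner. The block then takes up that array, so its estimates equal those without Cre replicate 1 (Srrm4 at 1.58 in both). The cause of the other changes was not tested. Bcl6 kept its direction in both probe sets and passed in no alternative over all probe sets. Of the 20 genes named over all arrays, 20 passed without EV replicate 1 and 19 with array weights. They were picked by their lowest p on these same arrays, so this is no separate test of them. Of the 24 named without it, 147 values over the alternatives no longer passed and 202 did, and none reversed. All these alternatives left out EV replicate 1. With EV replicate 1 included, Cxcr5 (0.06 against −0.74) and Pilrb1 (−0.02 against 1.07) did reverse. The replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at −0.115, −0.034 and −0.082, and 0 of 6 arrays correlated best with its own number. The replicate block gave 0 genes over all arrays, 577 at an unadjusted p under 0.05. Pseudocounts of a linear table were not run, as the values are already log2. Dim signals, which MAS5 leaves noisy, limit what can be seen for weakly expressed genes.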

Other observations

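All tests in this part were chosen after the result was seen, except the counts of other splits for all 6 arrays; the gene lists named first were also added after the data were seen.

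Genes of amino acid supply and the ATF4 response were lower in Cre without EV replicate 1, with a median of −0.45 over 28 genes, 25 of them below 0 and 10 past the threshold over all genes in limma. Asns fell 1.88-fold, the branched-chain aminotransferase gene Bcat1 1.63-fold, the amino acid carrier genes Slc7a5 1.55-fold and Slc7a1 1.44-fold, the mitochondrial folate enzyme genes Shmt2 1.5-fold and Mthfd2 1.43-fold, and the translation inhibitor gene Eif4ebp1 1.54-fold. Atf4 itself differed the other way, by 1.22-fold, without passing. This list was written after Asns, Slc1a4 and similar genes were seen to fall on these arrays, so no p is given for it. With all 6 arrays the median was −0.12, and only Aars, alanyl-tRNA synthetase, at −0.44 (SE 0.12), and Atf4, at 0.41 (SE 0.14), had groups that did not overlap among the 5 members with the lowest p. EV replicate 1 lay below EV replicates 2 and 3 in this list by a median of −0.71.

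Plasmacytoid dendritic cell markers had a median of 0.30 over 12 genes without EV replicate 1, and 1 passed over all genes, Siglech, which rose 1.71-fold. With all 6 arrays their median was 0.01 and their mean −0.04. This list too was written after genes of the kind were seen, and no p is given for it. Siglech read 12.74 on EV replicate 1, 9.998 and 10.09 on EV replicates 2 and 3, and 10.67 to 10.89 in Cre. Several of these genes, Tcf4, Spib and Irf8 among them, are also B lineage transcription factors on the fixed list. Cdkn2a, named after its values were seen, read 3.97 on EV replicate 1 and 5.57 to 6.25 on the other arrays.

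The distance of EV replicate 1 from the other arrays had several technical explanations that its values speak against. RNA degradation would raise the 3′ to 5′ ratio of all control transcripts, and this was highest on EV replicate 1 for 1 of 4. Lyz2-rich phagocytes or granulocytes in the culture would bring Lyz2 and other abundant transcripts. On EV replicate 1, 0 of 7 such genes lay above the dim limit, with Lyz2 at 5.14 beside Tyrobp at 12.52. This does not cover other myeloid cells, and 7 of 8 myeloid markers lay above EV replicates 2 and 3 there, by a list median of 1.17. A Cre array under an EV label would lack Bcl6, which lay 4.14 above the highest Cre array. Lower cytokine and STAT5 signalling than in EV replicates 2 and 3 stays open and was not decided. That list lay lower by a median of −0.64, below all of 10000 random lists matched on level, as this explanation predicts. The MYC list (−0.76) and the ATF4 list (−0.71) also lay below all their random lists. The shift is therefore not particular to the cytokine list.

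For the 7 lists that passed without EV replicate 1, a scaling difference that depends on signal level is argued against, since 7 of 7 still passed in the same direction after quantile normalization. A state that EV replicate 1 shared with the Cre arrays, apart from Bcl6, may account for part of the shifts. The correlations given next cannot tell it from a feature common to EV replicates 2 and 3 alone, which would also raise them. Cre minus EV replicate 2 correlated across genes with EV replicate 1 minus EV replicate 3 at 0.251, and with EV replicates 2 and 3 exchanged at 0.402, although these pairs share no array; genes are not independent replicates. Against the shared mean of EV replicates 2 and 3 the correlation was 0.487 (simulated with no effect 0.466) and the covariance 0.0872 (simulated 0.0196). The simulation gave EV replicate 1 the spread of the other arrays and held no outlying array. The simulated correlation is therefore not the level expected with no effect for these arrays. An effect of Bcl6 deletion on these lists also stays open, as does one of Cre itself, for which there was no control. EV replicate 1, with the most Bcl6, and the Cre arrays, with the least, both differed from EV replicates 2 and 3 in the same direction. Both differences are taken from those same EV arrays, so some agreement is expected with no effect and decides nothing here.

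Other splits of the arrays were too few for a share under 0.05. Over all 6 arrays the real count is 0 genes, so that 10 of 10 splits reach it by construction and nothing is tested; the highest other count was also 0. At least 2 lists passed in 7 of 10 splits, the highest other having 9, when EV replicate 1 was set with Cre replicates 1 and 3. Such list calls are therefore not particular to the real grouping, and their cause was not tested. Without EV replicate 1, 1 of 10 splits gave 166 genes, the real one, and the highest other gave 0. Of lists, however, the split that set Cre replicates 1 and 3 against the rest gave 7, as many as the real one, and 2 further splits gave 4.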
